A study of Synechocystis sp. PCC 6803 with 13 samples.

How the data were processed

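Total RNA from Synechocystis cultures was reverse-transcribed into Cy3-labelled cDNA and hybridised to one-colour Agilent arrays, per the labels' protocols. The 13 samples formed 4 groups named by the labels, the control strain and ΔsigCDE in standard light and after 30 min of high light. Each scanner file held 15744 spots, of which 536 were control spots. Spot intensities, as deposited, were produced with Agilent Feature Extraction 10.7.3, per the submitters' processing notes. The processed signal used here is background-corrected and on a linear scale, per the file headers. A second table deposited by the authors held log2 values for 3321 identifiers, of which 3263 matched the scanner files. Each of its 13 columns correlated best with the scanner values of its own array (r = 0.998 to 0.999), and its column medians were 10.04 to 10.08. The method used to scale that table is not given in the sources used here.

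Control spots and spots marked as non-uniform or as population outliers were left out, which left 54 probes without a value on at least 1 array. The 15208 remaining spots represented 8091 probes, 7117 with 2 spots and 974 with 1, and spots of a probe were averaged. Values were log2 of the processed signal minus the 75th percentile over the non-control probes of the array. A probe was kept if its signal was well above background on every array of at least 1 group, which kept 8033 probes and left out 58. Probes of a gene were then averaged on the log2 scale. The 3259 genes tested came from 3264 identifiers, of which 61, 1611, 1560 and 32 had 1, 2, 3 and 4 probes. A mean over probes understates a change that only part of a transcript shows. Genes with called probes in both directions numbered 0 and 1 for the strain comparisons in standard and high light, 4 and 1 for the light comparisons in the control strain and the mutant, and 0 for the difference between them. Where every probe of a gene was not well above background in 1 group, the change was given as a bound. That bound set the mean of the brighter group against the mean, per array, of the higher of the dimmest well-detected signal and the gene's own value.

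Group means were fitted with limma 3.58.1 in R 4.3.3 over all 13 arrays (9 residual degrees of freedom), with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over 3259 genes. A gene was called at an adjusted p below 0.05. The 5 comparisons were mutant against control strain in each light condition, high against standard light in each strain, and the difference of the light response between strains. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 33 lists tested, and again with an estimated correlation and with fry. Camera compares the members of a list with all other genes. A list of transposase genes could not be formed because the files give no products, and the ribosomal protein list was a fallback of 30 genes. The comparisons, the lists, the rule for named genes and all but 2 of the alternatives were set before the data were examined. Named genes were, per comparison, the 10 with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, the 10 largest for the difference of the light response, and the 9 sigma factor genes. To these came up to 4 called members of each list, or the 2 members with the smallest p where a described list had none. Not every gene the rule allows is named in the text. Genes of unknown product are given by identifier.

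The array identifiers are not paired with gene names in the files, and 0 of the 3264 matched the reference table of 3347 genes. Symbols therefore come from the lists, which use general knowledge of the CyanoBase nomenclature. As a check made after the values were seen, probe positions were compared with the coding length of the reference gene of the same symbol. Of 377 named members 133 shared a symbol with exactly 1 reference gene, and for 128 of these (96.2%) every probe position lay inside the coding length, against 62.0% for shuffled pairs. No genome coordinates are given, since no genome of the array's design was used here.

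The labels give replicate numbers and the slide of each array. Control replicate 4 in standard light was the only array on slide 3. In standard light, arrays of both strains with the same number deviated together from their group means (correlations of 0.486 to 0.546 in 3 of 3 pairs), so the numbers were taken to pair the samples in that comparison. With the replicate number as a block, 972 genes were called there in place of 746, and 11 lists in place of 6. Control replicate 4 is the only array with its number, so this block also takes it out of the comparison. Leaving out that array alone gave 852 genes and 10 lists. The same steps were tested on simulated data with the spread of the real groups, in which 200 of 3259 genes were changed by 4 sizes, 50 genes each. For the strain comparison in standard light 34 of 50 changes of 0.5 (log2) and 47 of 50 changes of 1 were recovered, and 5 of 185 calls were false. For the strain comparison in high light these numbers were 29, 47 and 11 of 185. They were 31, 47 and 14 of 191 for the light comparison in the control strain, and 22, 48 and 13 of 181 in the mutant. For the difference of the light response they were 18, 44 and 8 of 164. A simulated list shifted by 1 (log2) was called in all 5 comparisons, and 0 unshifted lists were. The simulated genes varied independently, whereas members of real lists vary together, with an estimated correlation of 0.76 for the ribosomal proteins. The simulation therefore does not show how often camera calls an unchanged real list.

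Alternatives were other background corrections and scalings, the authors' deposited table, other filters on dim probes, the slide and the replicate number as blocks, fits within a slide or within the groups compared, other variance models, the brightest probe of each gene, a 2-fold threshold, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.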

Results

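Transcript levels were measured in the unicellular cyanobacterium Synechocystis sp. PCC 6803 with one-colour Agilent microarrays. The glucose-tolerant control strain was compared with ΔsigCDE, a mutant lacking the group 2 sigma factors SigC, SigD and SigE, which are exchangeable subunits that direct RNA polymerase to promoters. Cells of each strain were taken from standard growth light, at a photosynthetic photon flux density (PPFD) of 40 µmol m-2 s-1, or after 30 min at 750 µmol m-2 s-1, called high light here. The submitters describe 3 to 4 independent experiments per condition, and the 13 arrays gave n = 4 for the control strain in standard light and n = 3 for each of the other 3 groups. The arrays held 8091 probes for 3264 gene identifiers, and 98.1% to 99.96% of the probes per array were well above background. The 75th percentile of the signal lay between 1380 and 4597 units, and no spot was saturated. The lowest percentile belonged to control strain replicate 4 in standard light, the only array on its slide and scan day. Correlations between arrays of a group, taken across genes, were 0.974 to 0.998. The number of arrays limits the precision of every value. Values are log2 differences ± standard error (SE) between group means of signals scaled to the 75th percentile of each array. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 3259 genes.

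The deleted genes were examined first, as a check of the labels. In all 6 mutant arrays sigE (sll1689) and sigC (sll0184) had lower signals than in all 7 control arrays. For sigE the difference was -3.21 ± 0.16 in standard light (adjusted p = 6.8e-08) and -3.28 ± 0.17 in high light (adjusted p = 4.7e-08). For sigC it was -0.46 ± 0.08 (adjusted p = 0.00193) and -0.58 ± 0.09 (adjusted p = 5.2e-04). The sigD (sll2012) signal differed by -1.65 ± 0.17 in standard light (adjusted p = 2.1e-05) and by -3.56 ± 0.18 in high light (adjusted p = 4.7e-08). The probes of a gene differed: the sigE probe at position 950 gave -5.81 ± 0.18 in standard light, and the probe at position 434 gave -0.76 ± 0.15. For sigD, the probes at positions 622 and 699 gave -2.51 ± 0.18 and -2.59 ± 0.18 in standard light and -5.24 ± 0.19 and -5.16 ± 0.19 in high light. The sigD probe at position 1 gave 0.16 ± 0.22 and -0.26 ± 0.24, with adjusted p-values of 0.706 and 0.482. With the brightest probe in place of the mean, the sigD calls were lost (adjusted p = 0.727 and 0.492 in standard and high light), as was the sigC call in standard light (adjusted p = 0.0997). The 3 sigC probes gave -0.32 ± 0.13, -0.45 ± 0.11 and -0.60 ± 0.11 in standard light. The labels do not give the part of each gene that was replaced, and a probe outside it checks nothing, so the small sigC difference neither bears out nor contradicts the label. No mutant array had the signal of the control strain at the later sigD and sigE probes.

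**Figure D1:**
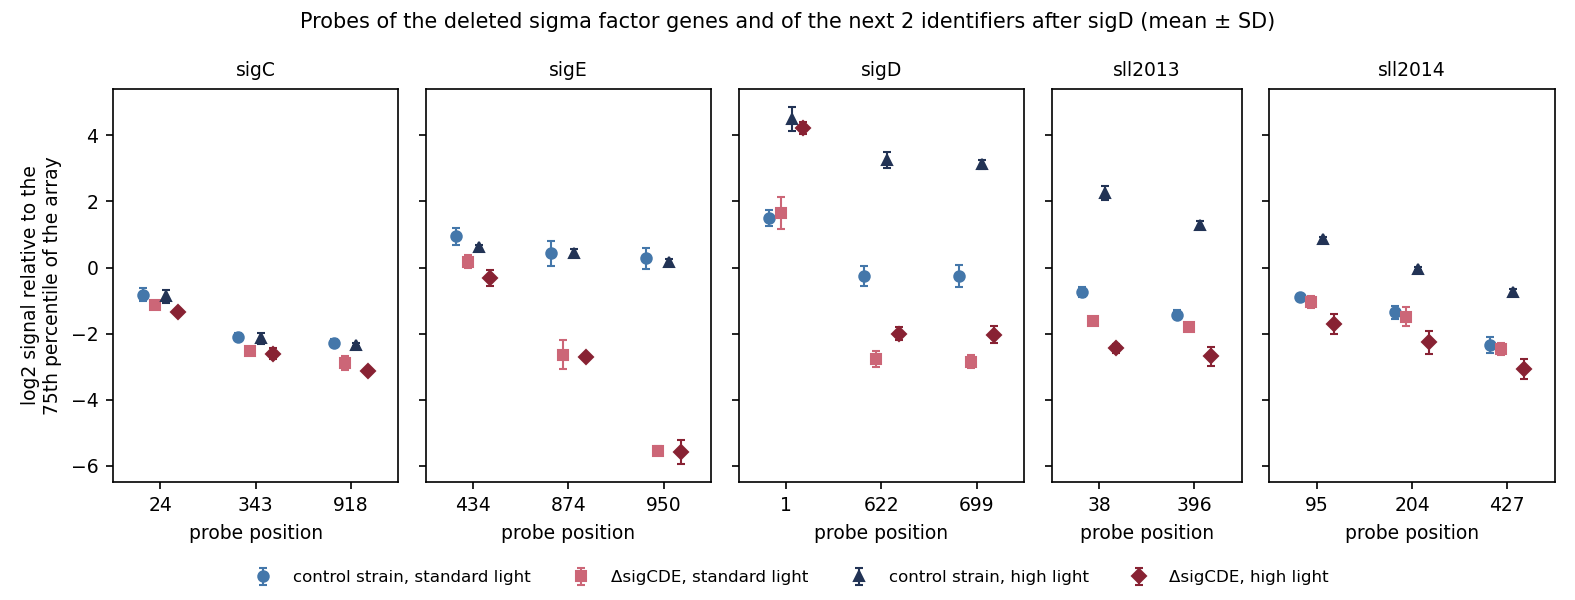
Log2 signal relative to the 75th percentile of the array (vertical axis, mean ± SD) for each probe of sigC, sigE, sigD and the next 2 identifiers, sll2013 and sll2014, against the position of the probe in the gene (horizontal axis), for the 4 groups with n = 4 in the control strain in standard light and n = 3 elsewhere. The sigD probe at position 1 rose in high light in both strains, by 3.01 ± 0.22 in the control strain and 2.59 ± 0.24 in the mutant, whereas the mutant points at positions 622 and 699 stayed below those of the control strain in both light conditions.

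The mutant was compared with the control strain in standard light to find transcripts that depend on the 3 sigma factors during growth. In ΔsigCDE 10 of 15 genes for breaking down sugars, 8 of 13 for respiration and 6 of 7 for the hydrogenase were lower, 1 gene for breaking down sugars was higher, and 9 of 10 genes for ATP synthase, 6 of 12 for the carboxysome and Rubisco and 7 of 15 for the phycobilisome were higher. By camera all 6 lists were called, and with an estimated correlation only sugar catabolism and respiration were (adjusted p = 0.0331 for each, against 0.125 for the hydrogenase, ATP synthase and carboxysome lists and 0.513 for the phycobilisome). The largest fall among the named metabolic genes was in tal (slr1793), the transaldolase of the oxidative pentose phosphate pathway, which was 4.50-fold lower (-2.17 ± 0.08, n = 3 against n = 4, adjusted p = 4.4e-09). The 6-phosphogluconate dehydrogenase gene gnd (sll0329) was 3.53-fold lower, and ctaC (slr1136), for a subunit of the terminal cytochrome c oxidase, was 2.56-fold lower. Transcripts of pgr5 (ssr2016), a protein of cyclic electron flow around photosystem I, were 4.29-fold higher. In all, 746 of 3259 genes differed at an adjusted p below 0.05, 373 higher and 373 lower in the mutant, and 72 of them differed by at least 2-fold, 16 higher and 56 lower. The even split depended on the fit. Of the called genes 25.8% were higher within slide 1, 36.0% with only the groups compared and 54.4% without control replicate 3 in standard light.

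Of the 15 measured genes on the list for sugar catabolism, 1 rose and 10 fell (1 and 11 when adjusted over the list alone; camera adjusted p = 5.1e-07). Besides tal and gnd (-1.82 ± 0.09), these included opcA (slr1734), which activates glucose-6-phosphate dehydrogenase (-1.24 ± 0.19), and glgX (slr0237), for a glycogen debranching enzyme (-1.11 ± 0.15). Of 13 genes for respiratory oxidases and dehydrogenases, 8 fell and none rose (10 fell when adjusted over the list alone; camera adjusted p = 1.9e-06). They included ctaC (-1.36 ± 0.14), ctaD (slr1137, -1.19 ± 0.09) and cydA (slr1379), for the bd-type quinol oxidase (-1.04 ± 0.08). Of the 7 genes of the bidirectional hydrogenase, 6 fell (7 when adjusted over the list alone; camera adjusted p = 3.9e-05), with hoxE (sll1220) at -0.71 ± 0.11 and hoxY (sll1224) at -0.62 ± 0.13. With an estimated correlation, sugar catabolism and the respiratory list kept their calls (adjusted p = 0.0331 for each), and the hydrogenase list did not (adjusted p = 0.125 with an estimated correlation).

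Of 10 ATP synthase genes, 9 rose (10 when adjusted over the list alone; camera adjusted p = 1.8e-05; adjusted p = 0.125 with an estimated correlation). The genes atpH (ssl2615) and atpI (sll1322) rose by 0.61 ± 0.10 and 0.60 ± 0.10. Of 12 genes for the carboxysome and Rubisco, 6 rose (9 when adjusted over the list alone; camera adjusted p = 0.00114; adjusted p = 0.125 with an estimated correlation). The shell protein genes ccmK4 (slr1839) and ccmK3 (slr1838) rose by 0.60 ± 0.12 and 0.46 ± 0.09. Of 15 phycobilisome genes, 7 rose (7 when adjusted over the list alone; camera adjusted p = 0.00222; adjusted p = 0.513 with an estimated correlation). They included the linker genes cpcG2 (sll1471, 1.26 ± 0.16) and cpcC1 (sll1580, 0.47 ± 0.10). The cpcC1 (sll1580) call was lost with quantile normalization (adjusted p = 0.0982) and with the authors' deposited values (0.119), and its adjusted p over all alternatives was 0.00255 to 0.119. The cpcG2 (sll1471) call was lost when the brightest probe stood for the gene (adjusted p = 0.352). The pgr5 difference was 2.10 ± 0.19, and the high-light-inducible gene hliB (ssr2595) rose by 1.16 ± 0.19. Among the sigma factor genes outside the deletion, sigI (sll0687) rose by 1.15 ± 0.13 and sigG (slr1545) by 0.43 ± 0.12. The sigI call was lost with the brightest probe (adjusted p = 0.395). The sigG call (adjusted p = 0.0240) was lost without control replicate 2 or without any 1 of the 3 mutant arrays in standard light, with adjusted p-values of 0.0544 to 0.0730, with quantile normalization (0.0878) and with the authors' deposited values (0.0684).

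Other genes moved within lists that were not called as a whole. On the list for glycogen and polyhydroxybutyrate synthesis 2 genes rose and 4 fell of 8 (2 and 4 when adjusted over the list alone), and phaC (slr1830), the polyhydroxybutyrate synthase gene, fell by 1.20 ± 0.12 (adjusted p = 1.8e-05). On the list for type IV pili 2 rose and 3 fell of 14, with the same counts when adjusted over the list alone. The major pilin gene pilA1 (sll1694) rose by 1.10 ± 0.19 and pilC (slr0162) changed by -0.69 ± 0.10. The flavodiiron gene flv3 (sll0550) changed by -0.94 ± 0.16, the only called member of its list of 5, over all genes and when adjusted over the list alone. Among identifiers without a name here, slr0364 and slr0366 rose most (2.33 ± 0.19 and 2.20 ± 0.22), and sll1675 and sll0584 changed by -1.83 ± 0.11 and -1.73 ± 0.11. With the slide as a block 898 genes were called, and 124 and 351 within slides 1 and 2, where fewer arrays entered. All 6 called lists kept the sign of their median in these fits, and the sugar catabolism median was -0.45, -0.47 with the block, and -0.44 and -0.50 within slides 1 and 2. Replicate numbers paired the samples in this comparison, and with the replicate number as a block 11 lists were called in place of 6, all 6 included. That block and the slide fits also leave out control replicate 4, which is alone in its number and on its slide. Without control replicate 4 alone, 852 genes and 10 lists were called, so the gain with the block cannot be credited to the pairing as a whole. A fit of the standard-light arrays alone called 292 genes.

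**Figure D2:**
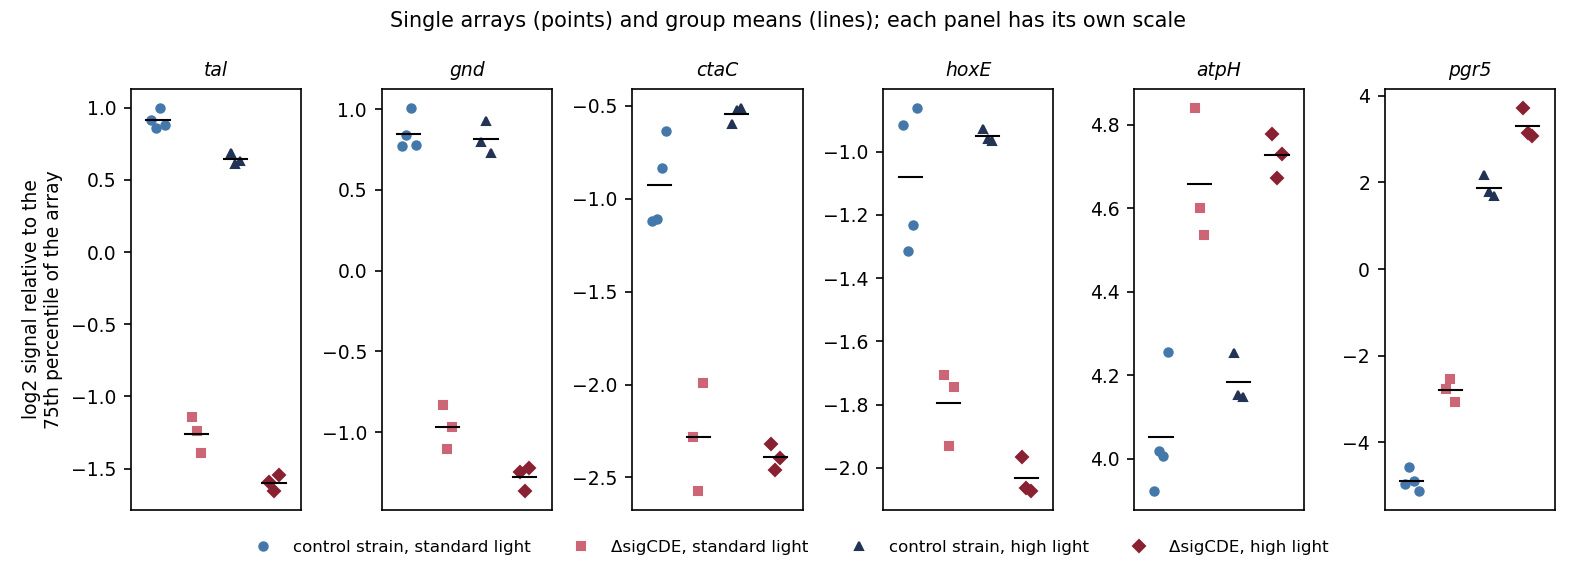
Log2 signal relative to the 75th percentile of the array (vertical axes, 1 scale per panel) for tal, gnd, ctaC, hoxE, atpH and pgr5 in each of the 13 arrays (points) with group means (lines), for the control strain and ΔsigCDE in standard and high light. In both light conditions each mutant point for tal, gnd, ctaC and hoxE lies below the points of the control strain, and those for atpH and pgr5 lie above.

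After high light the strain comparison asks which transcripts depend on the sigma factors under light stress. In ΔsigCDE 9 of 15 genes for sugar catabolism, 8 of 13 for respiration and all 7 for the hydrogenase were lower, and 8 of 10 for ATP synthase and 1 for respiration were higher. Of these lists, all called by camera, only sugar catabolism was called with an estimated correlation (adjusted p = 0.0498, against 0.0916, 0.101 and 0.346 in the order given). The largest difference of all was a 20.2-fold lower signal of sll2013 (-4.33 ± 0.12, n = 3 against n = 3, adjusted p = 1.3e-10), the identifier that follows sigD by number. Transcripts of tal were 4.72-fold lower, those of gnd 4.27-fold lower and those of ctaC 3.60-fold lower. Of 3259 genes 916 differed, 403 higher and 513 lower in the mutant, and 87 by at least 2-fold, 24 higher and 63 lower. The count was 603 without control replicate 2 in high light, and 37.3% of these genes were higher, against 44.0% with all arrays. This share was 23.3% within slide 1 and 50.4% with array weights.

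Sugar catabolism had 9 genes lower of 15 and none higher (9 lower when adjusted over the list alone; camera adjusted p = 1.9e-06; adjusted p = 0.0498 with an estimated correlation). The changes of tal and gnd were -2.24 ± 0.09 and -2.09 ± 0.10, that of opcA was -1.25 ± 0.20, and that of pfkA (sll1196), for a phosphofructokinase, was -0.98 ± 0.13. All 7 hydrogenase genes fell, also when adjusted over the list alone (camera adjusted p = 7.1e-06; adjusted p = 0.101 with an estimated correlation). Examples were hoxU (sll1223, -1.22 ± 0.15) and hoxE (-1.08 ± 0.12). Of 13 respiratory genes 1 rose and 8 fell (1 and 10 when adjusted over the list alone; camera adjusted p = 8.3e-05; adjusted p = 0.0916 with an estimated correlation). The cytochrome oxidase genes ctaC, ctaD and ctaE (slr1138) changed by -1.85 ± 0.15, -1.52 ± 0.10 and -1.13 ± 0.09, and the ctaE call was lost with the brightest probe (adjusted p = 0.0815). Of 10 ATP synthase genes 8 rose, as many as when adjusted over the list alone (camera adjusted p = 5.5e-04; adjusted p = 0.346 with an estimated correlation), with atpG (sll1323) at 0.59 ± 0.14 and atpI at 0.56 ± 0.11.

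Sigma factor genes outside the deletion differed in both directions under high light. On that list, 4 of 9 genes rose and 5 fell, the 3 deleted genes included and with the same counts when adjusted over the list alone (camera adjusted p = 0.469). The genes sigI, sigH (sll0856) and sigG rose by 1.52 ± 0.14, 1.19 ± 0.26 and 0.66 ± 0.13, and sigF (slr1564) changed by -0.39 ± 0.09. The sigI call was lost with the brightest probe (adjusted p = 0.219). Smaller changes were those of sigA (slr0653), the principal sigma factor (-0.47 ± 0.15, adjusted p = 0.0334), and sigB (sll0306, 0.40 ± 0.14, adjusted p = 0.0486). The sigA call was lost without control replicate 1 or 3 or any 1 of the 3 mutant arrays in high light, with adjusted p-values of 0.0617 to 0.145. The sigB call was lost in 8 of the 13 fits that left out 1 array, with adjusted p-values of 0.0539 to 0.174, and also with quantile normalization (0.0540), with median centring (0.0646), with the slide as a block (0.0508), with the authors' deposited values (0.0528) and with the brightest probe (0.571). It was kept without control replicates 1, 3 or 4 in standard light, control replicate 1 in high light or mutant replicate 3 in high light.

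Genes of pigments and photosynthesis also differed one by one, on lists that were not called as a whole. Of 24 tetrapyrrole and chlorophyll genes 3 rose and 7 fell (camera adjusted p = 0.0809). Of 15 phycobilisome genes 1 rose and 2 fell (camera adjusted p = 0.734), and of 29 photosystem II genes none rose and 7 fell (camera adjusted p = 0.119). The heme oxygenase gene ho1 (sll1184), the magnesium chelatase gene chlH (slr1055), the phycobilisome linker gene apcC (ssr3383) and psbT (smr0001) of photosystem II changed by -0.61 ± 0.13, -0.76 ± 0.09, -0.74 ± 0.13 and -0.89 ± 0.18. The ho1 and chlH calls were lost with the brightest probe (adjusted p = 0.0677 and 0.0967). In the other direction, pgr5 rose by 1.42 ± 0.20, nblA2 (ssl0453), for a protein of phycobilisome degradation, by 0.90 ± 0.19 and the protease gene htrA (slr1204) by 0.94 ± 0.17. The iron-stress chlorophyll protein gene isiA (sll0247) rose by 1.08 ± 0.34 (adjusted p = 0.0330), a call lost without control replicate 1 or 2 or mutant replicate 2 or 3 in high light (adjusted p = 0.0943 to 0.142) and with the brightest probe (0.0543). The pilin gene pilA2 (sll1695) rose by 1.44 ± 0.14 and pilC changed by -1.05 ± 0.11. Among unnamed identifiers, slr0364 and slr0366 rose by 3.04 ± 0.20 and 2.49 ± 0.23, and sll2014 changed by -2.38 ± 0.15. With the slide as a block 1111 genes were called, and 90 and 711 within slides 1 and 2. The 4 called lists kept the sign of their median in these fits, and the hydrogenase median was -0.99, -0.88 with the block, and -0.74 and -1.04 within slides 1 and 2. A fit of the 6 high-light arrays alone called 1517 genes, and array weights gave 1727.

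The strain effects of both light conditions, which share no array, were set side by side. Of the genes higher in the mutant 209 were called in both conditions, where 46.1 would be expected for independent lists (Fisher's exact test, two-sided, p = 1.4e-111). Of the genes lower in the mutant 288 were called in both, where 58.7 would be expected (Fisher's exact test, p = 5.7e-188). Only 2 genes were called higher in standard and lower in high light, and 1 the other way round. The fold changes correlated across genes with r = 0.786, and genes are not independent replicates. The genes tal, gnd, ctaC, hoxE and slr0364 were called in the same direction in both conditions.

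The light comparison within the control strain asks which transcripts respond to 30 min of high light in the control background. All 4 genes for high-light-inducible proteins, 3 of 6 other photoprotection genes and 27 of 30 ribosomal protein genes rose, and all 12 genes for photosystem I, 13 of 15 for the phycobilisome and 13 of 24 for tetrapyrrole and chlorophyll synthesis fell, while 2 of the latter rose. Of 10 lists called by camera, these 6 among them, 0 were called with an estimated correlation, where the lowest adjusted p was 0.0858. The transcript of pgr5 was 109-fold higher (6.77 ± 0.19, n = 3 against n = 4, adjusted p = 1.2e-10), hliB was 52.4-fold higher, and psaK1 (ssr0390), for a photosystem I subunit, was 9.04-fold lower. In all 1273 genes differed, 410 higher and 863 lower in high light, and 237 by at least 2-fold, 85 higher and 152 lower. The median over all genes was -0.13, so a value of 0 on the scale of the 75th percentile lies 0.13 above the median gene. With quantile normalization the split was 546 higher and 562 lower, and with median centring it was 613 and 579. With the authors' deposited values 48.7% of the called genes were higher, against 32.2% here.

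All 4 genes for high-light-inducible proteins, which bind chlorophyll in stressed thylakoids, rose, also when adjusted over the list alone (camera adjusted p = 8.8e-08; adjusted p = 0.0858 with an estimated correlation). Changes were 5.71 ± 0.19 for hliB, 4.96 ± 0.18 for hliA (ssl2542), 2.37 ± 0.14 for hliC (ssl1633) and 1.18 ± 0.11 for hliD (ssr1789). On the list of other photoprotection genes 3 of 6 rose, as many as when adjusted over the list alone (camera adjusted p = 3.4e-04; adjusted p = 0.125 with an estimated correlation). They were pgr5, nblA1 (ssl0452, 4.07 ± 0.23) and nblA2 (3.88 ± 0.18). Of 11 carotenoid genes 5 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.00146; adjusted p = 0.164 with an estimated correlation). The phytoene synthase gene crtB (slr1255) rose by 1.38 ± 0.13, and the desaturase genes crtP (slr1254) and crtQ (slr0940) by 2.34 ± 0.16 and 1.53 ± 0.17. Of 16 genes against peroxide and superoxide 9 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 3.4e-04; adjusted p = 0.125 with an estimated correlation), and gpx2 (slr1992), for a glutathione peroxidase-like protein, rose by 2.21 ± 0.18. Of 12 protease genes 6 rose, also when adjusted over the list alone (camera adjusted p = 1.2e-04; adjusted p = 0.125 with an estimated correlation), among them ftsH2 (slr0228, 1.74 ± 0.11) and ftsH3 (slr1604, 1.69 ± 0.15), whose products act in photosystem II repair.

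Of 30 ribosomal protein genes 27 rose and none fell (28 rose when adjusted over the list alone; camera adjusted p = 2.1e-14; adjusted p = 0.327 with an estimated correlation), with rplJ (sll1745) at 1.20 ± 0.11 and rplA (sll1744) at 1.18 ± 0.17. Of 5 genes for the RNA polymerase core 2 rose (3 when adjusted over the list alone; camera adjusted p = 0.0438; adjusted p = 0.327 with an estimated correlation). That list lost its call with quantile normalization, with the slide as a block, and without control replicate 1 or 4 in standard light or any 1 of the 3 control arrays in high light. Its member rpoA (sll1818) rose by 0.74 ± 0.20 (adjusted p = 0.00974, 0.0551 with quantile normalization and 0.0513 with the authors' deposited values; 0.00182 to 0.240 over all alternatives). The only sigma factor genes called were sigD (3.30 ± 0.17) and sigB (0.40 ± 0.13), which rose, sigG (-0.79 ± 0.12) and sigF (-0.27 ± 0.08), which fell, with the same counts when adjusted over the list alone. The sigF (slr1564) call (adjusted p = 0.0196) was lost with quantile normalization (0.0550), with median centring (0.148), with the authors' deposited values (0.0525) and without control replicate 2 in high light (0.105), and its adjusted p over all alternatives was 0.00911 to 0.424. The sigB (sll0306) call was lost with quantile normalization (adjusted p = 0.0697), with the authors' deposited values (0.0693), with the brightest probe (0.930) and without control replicate 3 in standard light or control replicate 1 or 2 in high light, with adjusted p-values of 0.0604 to 0.123. Of 15 genes for inorganic carbon uptake 4 rose and 4 fell (5 and 5 when adjusted over the list alone). The bicarbonate transporter genes cmpA (slr0040) and cmpC (slr0043) rose by 1.58 ± 0.44 and 2.01 ± 0.62, and the cmpC call (adjusted p = 0.0205) was lost without control replicate 1 or 2 in high light (adjusted p = 0.0595 and 0.0656) and with the brightest probe (0.0536). The NADH dehydrogenase gene ndbC (sll1484) rose by 1.17 ± 0.11, a call lost with the brightest probe (adjusted p = 0.474).

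All 12 photosystem I genes fell, also when adjusted over the list alone (camera adjusted p = 8.8e-08; adjusted p = 0.327 with an estimated correlation), with psaK1 at -3.18 ± 0.15, psaL (slr1655) at -2.79 ± 0.16 and psaI (smr0004) at -2.54 ± 0.13. Of 15 phycobilisome genes 13 fell (13 fell and 1 rose when adjusted over the list alone; camera adjusted p = 8.8e-08; adjusted p = 0.177 with an estimated correlation). The linker genes cpcC2 (sll1579), apcE (slr0335) and apcC changed by -2.48 ± 0.11, -2.30 ± 0.11 and -2.29 ± 0.12. Of 24 genes for tetrapyrrole and chlorophyll synthesis 2 rose and 13 fell (3 and 15 when adjusted over the list alone; camera adjusted p = 0.0211; adjusted p = 0.428 with an estimated correlation). Among them hemF (sll1185), for coproporphyrinogen oxidase, changed by -2.28 ± 0.17, ho1 by -2.22 ± 0.12 and chlP (sll1091), for geranylgeranyl reductase, by -1.78 ± 0.12. The sugar catabolism list was not called (camera adjusted p = 0.323), but 5 of its 15 genes fell, as many as when adjusted over the list alone, among them glgP (sll1356), for glycogen phosphorylase (-1.50 ± 0.11), and pfkA (-1.48 ± 0.13). Of the unnamed identifiers, slr1544 and sll1483 rose by 5.57 ± 0.22 and 5.01 ± 0.17, and slr0870 changed by -3.06 ± 0.26. The signal of sll1240 was not well above background in high light and was at least 9.27-fold lower there (adjusted p = 6.1e-06). With the slide as a block 1410 genes were called, and 353 and 1140 within slides 1 and 2. All 10 called lists kept the sign of their median in these fits, and the photosystem I median was -2.02, -1.79 with the block, and -1.76 and -1.84 within slides 1 and 2. These fits leave out control replicate 4, and the replicate block, which leaves it out too, gave -1.81.

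The same light comparison within ΔsigCDE asks which transcripts respond without the 3 sigma factors. All 4 genes for high-light-inducible proteins, 3 of 6 other photoprotection genes and 25 of 30 ribosomal protein genes rose, and all 12 genes for photosystem I, 12 of 15 for the phycobilisome, 14 of 24 for tetrapyrrole and chlorophyll synthesis and 15 of 29 for photosystem II fell, while 2 tetrapyrrole and chlorophyll genes and 1 photosystem II gene rose. Of 10 lists called by camera, these 7 among them, 0 were called with an estimated correlation, where the lowest adjusted p was 0.0691 and that of photosystem II was 0.795. The photosystem II call was also lost in 6 of the 13 fits that left out 1 array. Transcripts of pgr5 were 68.4-fold higher (6.10 ± 0.20, n = 3 against n = 3, adjusted p = 1.0e-09), those of hliB 31.7-fold higher, and those of psaK1 11.6-fold lower. In all 1161 genes differed, 325 higher and 836 lower in high light, and 279 by at least 2-fold, 91 higher and 188 lower. The median over all genes was -0.15, and the split was 485 higher and 496 lower with quantile normalization and 553 and 505 with median centring. With the authors' deposited values 50.4% of the called genes were higher, against 28.0% here.

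All 4 genes for high-light-inducible proteins rose, also when adjusted over the list alone (camera adjusted p = 2.6e-08; adjusted p = 0.0691 with an estimated correlation), with hliB at 4.99 ± 0.20 and hliA at 4.15 ± 0.19. Of 6 other photoprotection genes 3 rose, also when adjusted over the list alone (camera adjusted p = 1.4e-04; adjusted p = 0.148 with an estimated correlation), and nblA1 rose by 4.49 ± 0.24. Of 11 carotenoid genes 5 rose, also when adjusted over the list alone (camera adjusted p = 2.9e-04; adjusted p = 0.148 with an estimated correlation), with crtP at 2.56 ± 0.17 and cruF (sll0814), of myxoxanthophyll synthesis, at 1.60 ± 0.11. Of 16 genes against peroxide and superoxide 8 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.00191; adjusted p = 0.148 with an estimated correlation), and gpx2 rose by 2.49 ± 0.20. Of 12 protease genes 5 rose (6 when adjusted over the list alone; camera adjusted p = 0.00115; adjusted p = 0.168 with an estimated correlation), with ftsH2 at 1.64 ± 0.12 and ftsH3 at 1.57 ± 0.16, and this list was not called with quantile normalization. Of 30 ribosomal protein genes 25 rose (27 when adjusted over the list alone; camera adjusted p = 1.1e-13; adjusted p = 0.341 with an estimated correlation), with rplA at 1.09 ± 0.19.

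All 12 photosystem I genes fell, also when adjusted over the list alone (camera adjusted p = 1.3e-08; adjusted p = 0.293 with an estimated correlation), with psaK1 at -3.54 ± 0.16 and psaL at -3.29 ± 0.17. Of 15 phycobilisome genes 12 fell (13 fell and 1 rose when adjusted over the list alone; camera adjusted p = 6.1e-09; adjusted p = 0.148 with an estimated correlation), with apcC at -3.31 ± 0.13, cpcC2 at -3.03 ± 0.12 and apcE at -3.00 ± 0.12. Of 24 tetrapyrrole and chlorophyll genes 2 rose and 14 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.00195; adjusted p = 0.341 with an estimated correlation), with ho1 at -3.25 ± 0.13, hemF at -2.94 ± 0.18 and chlP at -2.67 ± 0.13. Of 29 photosystem II genes 1 rose and 15 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0410; adjusted p = 0.795 with an estimated correlation). The genes psbV (sll0258) and psbO (sll0427), for extrinsic proteins of the oxygen-evolving complex, changed by -1.26 ± 0.12 and -1.20 ± 0.14. The photosystem II call was lost without control replicate 1 or 3 in standard light, mutant replicate 1 or 2 in standard light, or mutant replicate 2 or 3 in high light.

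Sigma factor genes had 2 rises and 2 falls, with the same counts when adjusted over the list alone, including sigB (0.80 ± 0.14), sigF (-0.79 ± 0.09), sigG (-0.56 ± 0.13) and the gene-level sigD signal (1.39 ± 0.18). The sigB call was lost with the brightest probe (adjusted p = 0.724). The bicarbonate transporter gene cmpB (slr0041) rose by 2.20 ± 0.53, and 5 genes rose and 4 fell of the 15 for inorganic carbon uptake (5 and 5 when adjusted over the list alone). Genes for sugar catabolism had 6 falls of 15, as many as when adjusted over the list alone (camera adjusted p = 0.306), with glgP at -1.93 ± 0.12 and pfkA at -1.92 ± 0.13. Of 7 hydrogenase genes 4 fell (5 when adjusted over the list alone; camera adjusted p = 0.113), with hoxH (sll1226) at -0.70 ± 0.17. The identifiers sll1483 and slr1544 rose by 5.07 ± 0.18 and 4.89 ± 0.23, sll1784 changed by -3.44 ± 0.14, and sll1240, not well above background in high light, was at least 9.34-fold lower (adjusted p = 3.7e-06). With the slide as a block 1453 genes were called, and 537 and 1042 within slides 1 and 2. All 10 called lists kept the sign of their median in these fits, and the photosystem I median was -2.48, -2.48 with the block, and -2.36 and -2.74 within slides 1 and 2.

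**Figure D3:**
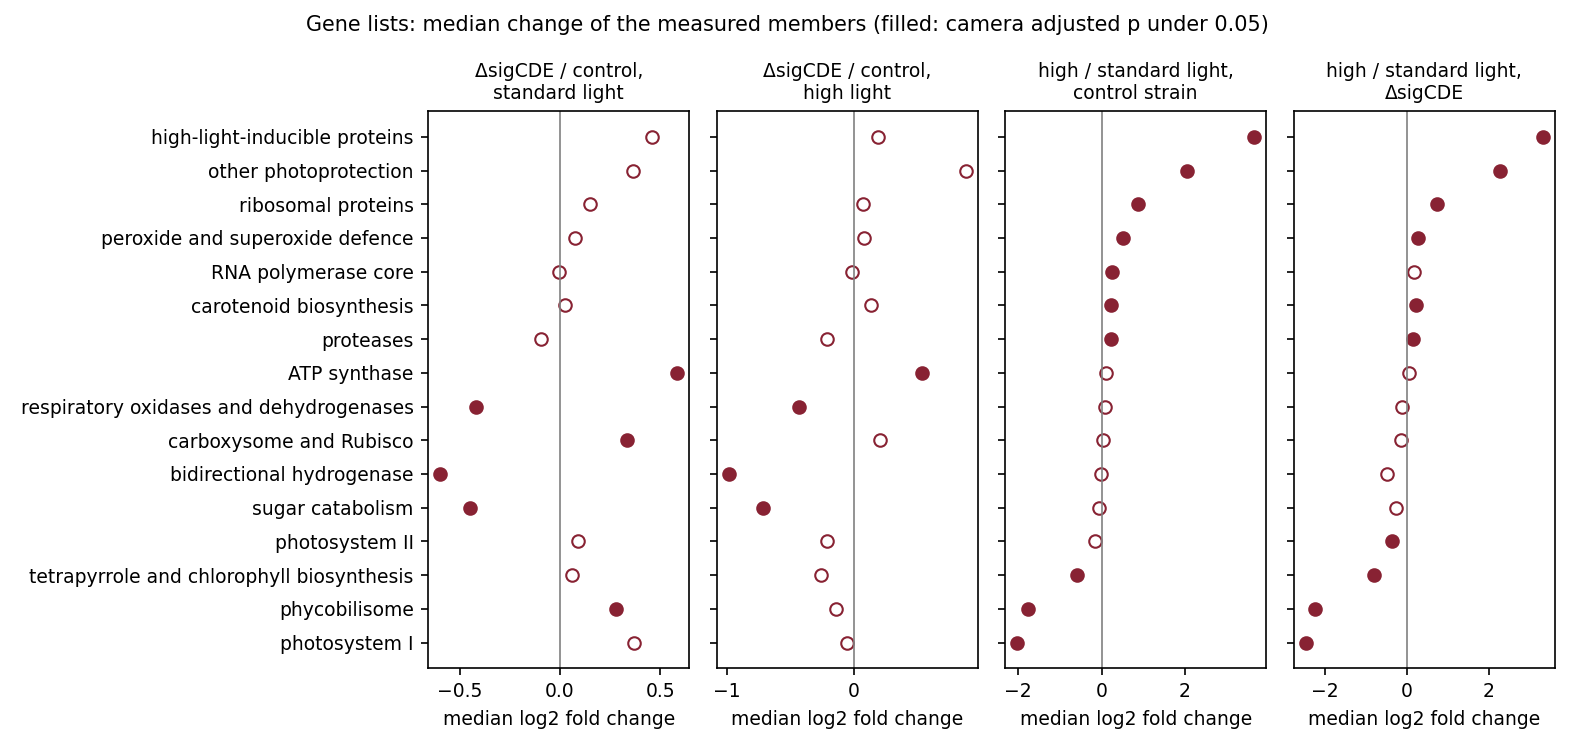
Median log2 fold change of the measured members (horizontal axes, 1 scale per panel) for each gene list called in at least 1 of the 4 comparisons shown, with filled points for lists called by camera and open points for lists not called. Photosystem I has medians of -2.02 and -2.48 in high light in the control strain and ΔsigCDE, and sugar catabolism has medians of -0.45 and -0.71 between strains; no called list changed the sign of its median with quantile normalization, median centring or the authors' deposited values.

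The light responses of both strains were set side by side and then tested for a difference. Among genes higher in high light 250 were called in both strains, where 40.9 would be expected for independent lists (Fisher's exact test, two-sided, p = 2.4e-191), and among genes lower in high light 611 were called in both, where 221 would be expected (Fisher's exact test, p = 2.1e-257). The fold changes correlated across genes with r = 0.920, and genes are not independent replicates. The comparisons share no array. The medians over all genes were -0.13 in the control strain and -0.15 in the mutant. This shift, common to both comparisons, can add to the overlap of lower genes, and fewer lower calls were shared with quantile normalization.

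The difference of the light response between strains (the interaction term, mutant minus control strain) was called for 4 genes, all with a negative difference. A negative difference, called a lower response here, can be a smaller rise, a lost rise or a larger fall in ΔsigCDE, and a higher response is the reverse. Higher responses were called too in some fits, 4 of 12 without control replicate 4 in standard light, 3 of 11 with the slide as a block, 8 of 39 with array weights and 1 of 6 with the replicate block. The slide block and the replicate block leave out control replicate 4 as well. Among the 4 genes were 3 with consecutive identifiers, whose induction was smaller or absent in the mutant. The gene sigD had a difference of -1.91 ± 0.25 (adjusted p = 0.00381), sll2013 of -3.72 ± 0.17 (adjusted p = 4.4e-08) and sll2014 of -2.24 ± 0.21 (adjusted p = 1.7e-04). In the control strain sll2013 and sll2014 rose by 2.86 and 1.56 in high light, and in the mutant they fell by 0.87 and 0.68. The fourth gene was ho1, whose product opens the heme ring on the way to phycobilin pigments, and which fell by 2.22 in the control strain and 3.25 in the mutant, a difference of -1.03 ± 0.17 (adjusted p = 0.0426). The ho1 (sll1184) call was lost in 10 of the 13 fits that left out 1 array, with adjusted p-values of 0.0593 to 0.198, and was kept without control replicate 4 in standard light, control replicate 1 in high light or mutant replicate 2 in high light. It was also lost with quantile normalization (adjusted p = 0.145), with the authors' deposited values (0.118) and with the brightest probe (0.242), which also ended the sigD call (adjusted p = 0.892). At an unadjusted p under 0.05, 296 genes differed.

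By camera 5 lists were called, all with a negative difference, and none kept its call with an estimated correlation. They were photosystem II with a median difference of -0.28 (camera adjusted p = 2.8e-06; adjusted p = 0.50 with an estimated correlation), the phycobilisome with -0.55 (2.0e-06; adjusted p = 0.50 with an estimated correlation), photosystem I with -0.34 (0.00761; adjusted p = 0.955 with an estimated correlation), tetrapyrrole and chlorophyll synthesis with -0.22 (0.00130; adjusted p = 0.50 with an estimated correlation) and the hydrogenase with -0.37 (0.00544; adjusted p = 0.50 with an estimated correlation). For photosystem I, the phycobilisome and tetrapyrrole and chlorophyll synthesis the negative difference was a larger fall in the mutant. Their medians in high light were -2.02, -1.75 and -0.58 in the control strain and -2.48, -2.24 and -0.81 in ΔsigCDE. Of the members of the 5 lists only ho1 passed over all genes. Among those that did not, apcC had -1.02 ± 0.18 (adjusted p = 0.0547), apcE -0.70 ± 0.16 (0.206), psbL (smr0007) -0.49 ± 0.12 (0.285), psbJ (smr0008) -0.38 ± 0.12 (0.386), hoxU -0.67 ± 0.20 (0.364), psaE (ssr2831) -0.88 ± 0.36 (0.492) and psaD (slr0737) -0.61 ± 0.27 (0.523). The apcC (ssr3383) difference was called without control replicate 4 in standard light (adjusted p = 0.0477), without mutant replicate 2 in high light (0.0260), with median centring (0.0355), with normexp on the median signal (0.0277), with the slide as a random block (0.0406), with trend and robust (0.0292) and with array weights (0.0247); over all alternatives its adjusted p was 0.0247 to 1.00. Outside these lists ndbC had 0.78 ± 0.16 (adjusted p = 0.127, and 0.0477 without control replicate 4 in standard light for sll1484) and hliA -0.81 ± 0.26 (adjusted p = 0.402). When adjusted over the list alone, lower responses were called for 7 phycobilisome genes, 3 tetrapyrrole and chlorophyll genes, 1 hydrogenase gene and 0 genes of both photosystem lists. With the slide as a block 11 genes were called, 1 within slide 1 and 14 within slide 2, and 12 without control replicate 4 in standard light. All 5 lists kept the sign of their median in these fits, and the phycobilisome median was -0.55, -0.66 with the block, and -0.64 and -0.71 within slides 1 and 2. The photosystem I median moved more, from -0.34 to -0.53 with the block and to -0.60 within each slide. That of tetrapyrrole and chlorophyll synthesis moved the other way, from -0.22 to -0.17 with the block and to -0.18 and -0.16 within slides 1 and 2. These slide fits leave out control replicate 4, as does the replicate block, with which the photosystem I median was also -0.53. An effect of the slide can thus not be told apart from the loss of that array.

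**Figure D4:**
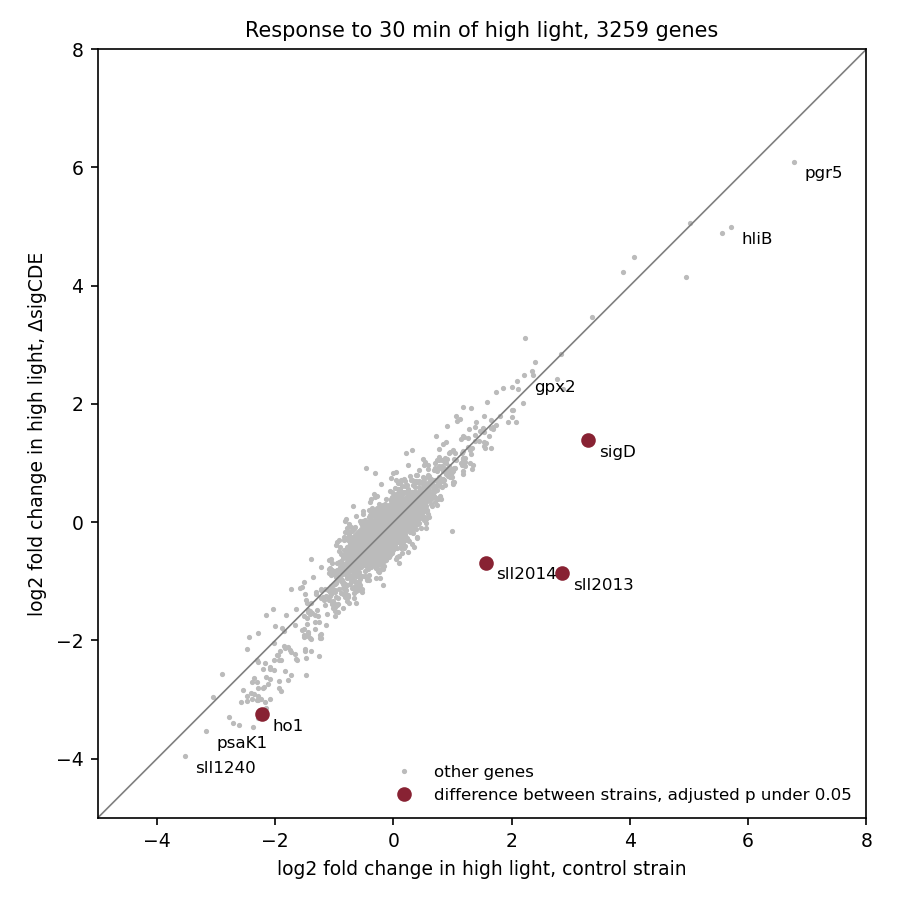
Log2 fold change between high and standard light in the control strain (horizontal axis) and in ΔsigCDE (vertical axis) for each of the 3259 genes, with the line of equal response and larger points for the 4 genes whose response differed between strains. Most genes lie near the line (r = 0.920 across genes), and sigD, sll2013 and sll2014 lie below it.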

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

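Of the tests in this part, those of the sigD transcript's start and of its later probes, those of single arrays and of scaling for the photosynthesis lists, and the regroupings without the additive effects, with and without parted pairs, were chosen after the result was seen.

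The light response differed between strains for 4 genes: sigD (-1.91), sll2013 (-3.72), sll2014 (-2.24), which have consecutive identifiers, and ho1 (-1.03). A candidate explanation is that the disrupted sigD (sll2012) locus cuts the transcript after its start, so that the genes after it lose a shared light response. The probe at sigD position 1 differed by only -0.42 ± 0.33 and still rose by 2.59 in the mutant, which argues against a lost response of the transcript's start, whereas the differences of -2.10 to -3.83 at the 7 later probes of sigD, sll2013 and sll2014 only restate the calls and support no explanation. The 3 nearest identifiers before sigD (sll2009, sll2010 and sll2011, chosen for their numbers) had differences of which -0.21 was the largest in size, which argues against an effect on both sides of the locus, and sll2015 after it had -0.45 ± 0.21 (adjusted p = 0.534). Whether the lost rise of sll2013 and sll2014 reflects the disrupted locus or the missing sigma factors stays open, because no single mutant was analysed here and genome order was taken from identifier numbers.

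By camera the difference of the light response was called for the lists of photosystem II (adjusted p = 2.8e-06), the phycobilisome (2.0e-06), tetrapyrrole and chlorophyll synthesis (0.00130) and photosystem I (0.00761). Of their 80 members 68 (85%) had a negative difference, with a median of -0.29, against 56.9% of all genes. Between strains, the medians in standard and high light were 0.37 and -0.05 for photosystem I and 0.28 and -0.14 for the phycobilisome. They were 0.09 and -0.21 for photosystem II and 0.06 and -0.26 for tetrapyrrole and chlorophyll synthesis. By median, photosystem I and the phycobilisome were thus higher in the mutant in standard light. Photosystem I was not called there by camera (adjusted p = 0.0588), and the phycobilisome call (camera adjusted p = 0.00222) was lost with an estimated correlation (adjusted p = 0.513). In high light none of the 4 lists was called between strains by camera. Genes outside the lists matched on mean signal (the nearest 20 per member, without a limit on distance) had a median of -0.043. This argues against a bias that depends on signal over the signals that the matched genes reach. How close the matches were for the brightest members was not measured. Leaving out 1 array ended the call of at most 1 of the 4 lists (photosystem I, without control replicate 2 or 3 in standard light), and quantile normalization or median centring ended 0. Chance is not excluded, since 42 of 100 regroupings of the strain labels that part the standard-light pairs called as many lists once the additive effects of strain and light were removed, and no list kept its call with an estimated correlation or with fry, so the stronger fall remains a hypothesis.

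Other splits of the same arrays were tested for each count of calls. In the control strain 1 of 35 splits, the real one, gave as many genes between light conditions (1273, highest other 727). That is the smallest share that 35 splits allow and is under 0.05, so chance is unlikely, without allowance for the several counts tested. In standard light 1 of 35 gave as many between strains (746, highest other 260), but replicate numbers pair these arrays and only 8 of the splits part all 3 pairs, too few for a share under 0.05. The splits that part 2, 1 or 0 pairs gave at most 191, 70 and 92 genes. For the strains in high light and the light conditions in the mutant, the 10 possible splits are too few for a share under 0.05. The real splits gave 916 and 1161 genes, as many as 1 of 10 in each case, and the highest other gave 0. For lists, chance is not excluded in the control strain (13 of 35 splits as large, 10 lists, highest other 14), and in standard light, where the pairs leave too few splits, 25 of 35 called as many (6 lists, highest other 18). With 10 splits, 9 called as many lists between strains in high light (4 lists, highest other 7) and 3 between light conditions in the mutant (10 lists, highest other 13), too few to test. For the difference of the light response, 7 of 100 regroupings of the strain labels within each light condition gave as many genes (4, highest other 1093) and 74 as many lists (5, highest other 15). These do not test chance, since 5 of the 6 other regroupings with as many genes mostly swapped the strain labels in 1 light condition and so carry the strain effect, a structure of the samples. With the additive effects of strain and light removed, 2 of 100 regroupings gave as many genes (4, highest other 82) and 61 as many lists (5, highest other 15), but these too ignore the pairs in standard light. When each also parted all 3 pairs, 1 of 100, the real one, gave as many genes (4, highest other 0), so chance is unlikely for that count. The count rests mainly on the deleted gene sigD and on sll2013 and sll2014, the identifiers after it. It therefore does not bear on ho1 or on other genes. For lists, 42 of 100 gave as many (5, highest other 14), so chance is not excluded for them.

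The difference of the light response was also called by camera for the hydrogenase list (adjusted p = 0.00544), but neither with an estimated correlation (adjusted p = 0.50 with an estimated correlation) nor by fry (adjusted p = 0.1004).

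Single arrays stood apart in the only group of 4, the control strain in standard light. Replicate 3 had a higher value than the others for ccmK4 (-0.021 against -0.37 to -0.32) and hoxU (-1.93 against -2.45 to -2.41), and replicate 2 a lower one for apcC (2.40 against 2.69 to 2.71). Replicate 1 was higher for sasA (-0.90 against -1.15 to -1.11). Replicate 4 was higher for psaD (4.87 against 4.0 to 4.15), lower for desB (-2.75 against -1.55 to -1.32), and had 98.1% of probes well above background against 99.8% to 99.96%. These were 7 of 98 values tested, where chance gives about 5%, and 3 of them rest on replicate 4, the array on its own slide.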

How the results depend on the processing

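The normexp correction on the median signal and the replicate block within the standard-light arrays were chosen after seeing the data, the former because the planned mean signal is not a column of the files used here, so that version was not run. The fit of only the groups compared gives no value for the difference of the light response.

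All but 1 of the named calls kept their direction under every alternative. Of 157 named calls, 157 were kept with normexp, with no filter on dim probes, with the slide as a random block, with the replicate block, with trend and robust and with array weights. Kept were 156 with the slide as a fixed block, 155 with median centring, 150 with quantile normalization, 150 with the deposited table and 138 with the brightest probe. All 154 that could be tested were kept with only probes well above background on all arrays. Leaving out 1 array kept 150 (without control replicate 2 in high light) to 157. With fewer arrays 111 and 142 were kept within slides 1 and 2, and 148 of 153 with only the groups compared. With the brightest probe the sigD (sll2012) difference between strains in standard light reversed to 0.16 (adjusted p = 0.727, against 7.2e-06 to 0.727 over all alternatives), because the brightest probe is the one at position 1, and 3 of 6 comparisons of deleted genes passed. Calls of sigD, sigB, sigC, sigI, isiA, cmpC, ndbC, ctaE, cpcG2, chlH, ho1 and hpt were among the 19 lost with that probe. All 35 called lists kept the sign of their median in the 8 settings compared.

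Counts of called genes that moved by over 1.5 times are given here, and where no cause is named the cause was not tested. Fewer arrays entered within slides 1 and 2, which gave 124 and 351 genes between strains in standard light and 1 and 14 for the difference of the light response. Within slide 1 there were 90 genes between strains in high light, and 353 and 537 between light conditions in the control strain and the mutant. Only the groups compared gave 292 between strains in standard light and 1517 in high light. Array weights gave 1727 between strains in high light and 39 for the difference of the light response, for which the slide as a fixed block gave 11 and the brightest probe 2. The slide block leaves out control replicate 4, and leaving out that array alone gave 12 for the difference. The 2-fold threshold, stricter by construction, gave 72, 87, 237 and 279 for the strains in standard and high light and the light conditions in the control strain and the mutant. It gave shared calls of 10 higher and 36 lower between strains and 72 and 140 between light conditions, and quantile normalization gave 386 shared lower calls.

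Leaving out each array gave 511 to 852 genes between strains in standard light, 603 (without control replicate 2 in high light) to 1127 in high light, 859 to 1393 between light conditions in the control strain, 837 to 1405 in the mutant, and 3 to 12 for the difference (12 without control replicate 4 in standard light). Lists numbered 6 to 10, 4 to 5, 9 to 12, 9 to 10 and 4 to 7 in that order, and all 6 deleted-gene comparisons passed throughout. An estimated correlation left 2, 1, 0, 0 and 0 lists, and fry, which compares no list with other genes, called 13, 14, 17, 17 and 0. The slide as a fixed block gave 11 lists between strains in standard light and 8 for the difference. Leaving out only control replicate 4, which that block also removes, gave 10 and 7.

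With the replicate block 11 lists were called between strains in standard light, 12 in place of 10 between light conditions in the control strain (ATP synthase and Calvin cycle added) and 8 for the difference of the light response, and in the standard-light arrays alone 12 lists and 1034 genes, 690 of the 746 among them. The block ended no call of a named gene or list, and gene counts were 972, 1264, 1521, 1538 and 6. It also leaves out control replicate 4, the only array with its number. Leaving out that array alone gave 852, 1127, 1393, 1405 and 12 genes. Outside standard light the numbers did not pair the samples, with correlations of deviations of -0.31 to 0.29 between strains in high light, -0.08 to 0.09 between light conditions in the control strain and 0.06 to 0.09 in the mutant. Each sample correlated best with its own number in 1, 0 and 3 of 3 cases, a hint for the mutant from the data. Between strains in high light, pairs of different numbers spanned -0.46 (mutant replicate 1 with control replicate 3) to 0.42 (mutant replicate 2 with control replicate 3). Arrays there may share deviations in a way that the numbers do not give, which was not tested. Signal over background limits few genes, since at least 98.1% of probes per array were well above background.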

Other observations

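The test reported in this part was set before its result was seen. In both light conditions 3 genes of the synthesis of tocopherol, a lipid antioxidant of the thylakoids, were lower in ΔsigCDE. Of 7 genes on the tocopherol and glutathione list 0 rose and 3 fell in standard light (1 and 3 when adjusted over the list alone; camera adjusted p = 0.187), and 1 rose and 3 fell in high light, as many as when adjusted over the list alone (camera adjusted p = 0.322). The homogentisate phytyltransferase gene hpt (slr1736) changed by -0.72 ± 0.14 and -0.89 ± 0.15, the tocopherol cyclase gene vte1 (slr1737) by -0.68 ± 0.11 and -0.59 ± 0.11, and the tocopherol methyltransferase gene tmt (slr0089) by -0.56 ± 0.09 and -0.76 ± 0.10. Both hpt calls were lost with the brightest probe, with adjusted p-values of 0.458 and 0.329. On the nitrogen list of 18, 1 gene fell in standard light and 2 in high light (1 and 2 when adjusted over the list alone), with gltB (sll1502), for glutamate synthase, at -0.68 ± 0.10 and -1.06 ± 0.11.

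Some genes of the circadian clock fell in high light in both strains. In the control strain 4 of 10 clock and output genes fell and 1 rose, as many as when adjusted over the list alone (camera adjusted p = 0.712). The genes kaiB1 (slr0757), kaiC1 (slr0758) and kaiB3 (sll0486) changed by -0.64 ± 0.10, -0.50 ± 0.11 and -0.45 ± 0.09, and the output kinase gene sasA (sll0750) by -0.58 ± 0.09. In the mutant 4 fell and 0 rose (4 and 0 when adjusted over the list alone; camera adjusted p = 0.626), with sasA at -0.61 ± 0.09 and kaiB3 at -0.60 ± 0.10, and kaiB1 was higher in the mutant than in the control strain in high light (0.67 ± 0.10). Of 13 chaperone genes 4 rose and 1 fell in the control strain (4 and 1 when adjusted over the list alone), and 2 rose and 2 fell in the mutant (2 and 1 when adjusted over the list alone), where the median of the list was -0.17 while its mean and its camera direction were above 0. The small heat shock gene hspA (sll1514) rose by 0.91 ± 0.16 and 1.07 ± 0.17. Of 4 desaturase genes desB (sll1441) rose by 0.88 ± 0.27 in the control strain and 1.35 ± 0.29 in the mutant. The former value was 0.54 without control replicate 4 in standard light, and its call was lost without control replicate 1 or 2 in high light (adjusted p = 0.0546 and 0.0576); over all alternatives its adjusted p was 0.000611 to 0.0787. Neither the clock, chaperone, nor desaturase list was called by camera in these comparisons, and differences between the strains' responses were not called for these genes.

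The mutant in standard light had higher values of some light-induced genes, among them pgr5 and hliB, and a hypothesis was that it resembles control cells in high light across all genes. The 4 control arrays in standard light were split so that no array was shared (6 assignments, 2 controls per side). The correlation across genes of the strain and light effects was then -0.161 to 0.0234, and no such resemblance was seen. The split leaves mutant and control arrays of the same replicate number on opposite sides, and their shared deviations can lower this correlation. The test therefore does not decide the hypothesis. With shared controls r was 0.0233, against 0.426 in 100 simulations of unchanged groups, which were drawn without the pairing by replicate number. The covariance was 0.00526 against a simulated 0.0126, a difference of -0.00738. Genes are not independent replicates.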
